A study of Homo sapiens with 2 samples.

How the data were processed

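Chromatin contacts of 2 libraries of MCF7 cells, an estrogen receptor positive breast cancer line, were compared. Per the labels, the groups were MED1 WT and MED1 6KR. The series' design text describes cells depleted of endogenous MED1, a Mediator subunit, that expressed HA-tagged wild-type or KR mutant MED1. Each group had 1 library, so no spread between replicates could be measured, no test between conditions was run and no p-value was computed. HiCAR joins Tn5 tagmentation of open chromatin to proximity ligation, so that 1 end of a read pair marks an accessible site. Per the labels, fixed nuclei were tagmented with Tn5, cut with CviQI, ligated with a splint oligonucleotide, cut with NlaIII, circularised and amplified by PCR. The ChIP-seq, CUT&RUN and RNA-seq of the wider study were not analysed here.

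The authors deposited 1 list of significant interactions per library, in bins of 10 kb per the labels. The build was hg38, per the submitters' processing notes. The aligner, the caller, its version and the filters on reads were not given in the sources used here. Per the file headers, each pair of bins has a read count, which is a whole number without scaling. The deposited expected column holds a background signal in reads for the same pair, never negative, and its model was not given in the sources used here. The deposited fdr column holds a q-value or an equivalent adjusted p-value. The deposited cluster column of −log10 p, and other cluster columns of size and summit per the file headers, group neighbouring pairs. The limits of the lists were tested on the files: at least 12 reads, observed over expected of at least 2, fdr below 0.01, and below 0.0001 for pairs without a listed neighbour. All pairs lay within 1 chromosome, on the 22 autosomes. A pair of bins that is missing from a list had no value here, so a pair listed in 1 library only cannot be read as a contact that is absent from the other.

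The WT list held 23189 pairs with 625998 reads, and the 6KR list held 15326 pairs with 415313 reads. These sums depend on how much was listed and are not library depths, which were not given in the sources used here. Relative depth was estimated from pairs listed in both libraries. The median 6KR over WT ratio was 0.860 for read counts of 1287 shared pairs with a mean of 50 or more reads, and 0.901 for expected counts of all 10146 shared pairs. Neither estimate separates depth from a change of contacts that is common to many pairs.

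Overlap was the share of pairs with both bins identical, with exact Clopper-Pearson 95% intervals. Its chance level came from 6 shifts of the 6KR list along the chromosomes with distances kept. Intervals of ratios came from the exact binomial interval of the 6KR share, and intervals of medians from order statistics. All intervals cover counting error only. The labels' protocol names no molecular identifiers, and neighbouring pairs of a cluster are not independent, so the true uncertainty is larger. Changes of contact strength were log2 of observed over expected, 6KR minus WT, over shared pairs.

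Genes came from a RefSeq table of GRCh38.p14, with 19126 protein-coding genes on autosomes. The design fixed before the data were examined called for the bin with the 5-prime end of each gene. The table used here has no strand, so the bins with either end of a gene stood for it, called gene-end bins below. Only 2817 genes, 14.7%, had both ends in 1 bin. Values per gene were log2 of (6KR pairs + 1) over (WT pairs + 1), and counts of genes with at least 2-fold fewer or more pairs were taken relative to the ratio of the list lengths, among genes with 10 or more pairs in at least 1 library. The genome sequence needed for GC content and CviQI sites of the bins was not used here, so that check was not run.

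The named genes followed a rule fixed before the data were examined: MED1 and ESR1, the 10 genes with the highest and the 10 with the lowest ratio among those with 10 or more pairs, the 5 genes with the most pairs in each library, and from each gene list the 2 highest and 2 lowest members with 5 or more pairs over both libraries. Genes that share a bin counted as 1 entry. For single interactions, the rule took the 3 with the most reads listed in both libraries and the 3 listed in each library alone. The 15 gene lists, with 436 entries, were also fixed before the data were examined. Of the entries, 434 matched the gene table and 425 were protein-coding genes on autosomes. The median of a list was placed among 10000 random lists of the same size matched on the number of pairs in 10 classes, which describes these libraries and is no test of the conditions. Pooled numbers count a pair once for each member it touches.

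Alternatives fixed beforehand were a stricter fdr of 0.0001, a minimum of 20 reads, lists of equal length, leaving out chromosomes 1, 3, 17 and 20 with known MCF7 amplifications, overlap within 1 bin, 1 pair per cluster, other bins around genes, a pseudocount of 3, a minimum of 20 pairs per gene and another scaling. Others were added after seeing the data, among them thinning of the WT list to the 6KR depth in 50 draws with the limits of the lists reapplied. Lists of equal length kept the whole 6KR list and the same number of WT pairs, those with the lowest fdr. Only WT thus lost its weaker pairs, which can shift values by itself, so this setting is no match of depth.

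The functions were tested on simulated data made from the WT list. In 5 simulations of the 6KR against WT comparison over 19126 genes, 200 genes had their pairs lowered. Of the changed genes with 10 or more pairs, 100% passed the limit at 2-fold and 100% at 4-fold. The reads of their pairs were lowered, and the median of 19 reads per WT pair, lowered 2-fold, falls below the limit of 12. The limits thus nearly fixed this outcome, which does not show how well 2-fold fewer pairs can be found. With no gene lowered, 0 to 1 genes had at least 2-fold fewer pairs, the median log2 change at shared pairs was 0.041, and the thinned WT list was 0.983 times as long as the simulated 6KR list. The ratio of list lengths was 0.862, against 0.661 in the deposited lists, and 69.5% of WT pairs were also in the 6KR list, against 43.8%. These simulations took the listed read counts as true means and drew no pairs from outside the WT list, so they vary less than real libraries. Both simulated lists had the limits reapplied, so the simulated WT list had already lost pairs near the limits. The deposited WT list kept 70.1% of its pairs when thinned to a depth of 0.860, so the simulated 0.862 does not show what depth alone does. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.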

Results

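Contacts anchored at open chromatin were mapped by HiCAR in MCF7 cells that expressed wild-type MED1 or the 6KR mutant, with 1 library each and no replicates. The WT list held 23189 pairs of 10 kb bins and the 6KR list 15326 pairs, with a median of 19 reads per pair in both. Median observed over expected was 4.75 in WT and 5.01 in 6KR. Neighbouring pairs formed 7500 clusters and single pairs in WT and 5095 in 6KR, the largest of 874 and 813 pairs. MED1 itself, on chromosome 17 at 39404285 to 39451263 (hg38), had 0 listed pairs in either library, so the lists hold no check of the labels. ESR1, which encodes the estrogen receptor, had 2 pairs in WT and 0 in 6KR.

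Every autosome carried fewer listed interactions in the 6KR library than in the WT library. Chromosome 20, whose long arm is amplified in MCF7 cells, held the most pairs in both, 5386 in WT and 4249 in 6KR, a ratio of 0.789 (95% interval 0.758 to 0.821). Chromosome 17 had 2210 and 1607 pairs, a ratio of 0.727 (0.681 to 0.776), and chromosome 3 had 1908 and 1343, a ratio of 0.704 (0.656 to 0.755). Chromosome 22 had the lowest ratio, with 48 pairs in WT and 14 in 6KR, 0.292 (0.149 to 0.538). Chromosomes 1, 3, 17 and 20 together went from 11120 to 8210 pairs, a ratio of 0.738 (0.717 to 0.760), and all others from 12069 to 7116, a ratio of 0.590 (0.573 to 0.607). Over the whole lists the ratio was 0.661 (0.648 to 0.675). List length depends on sequencing depth as well as on contacts, and with the WT list thinned to a depth of 0.860, an alternative chosen after seeing the data, the ratio was 0.943. Thinned to the other depth estimate, 0.901, the WT list stayed 1.16 times as long as the 6KR list.

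**Figure D1:**
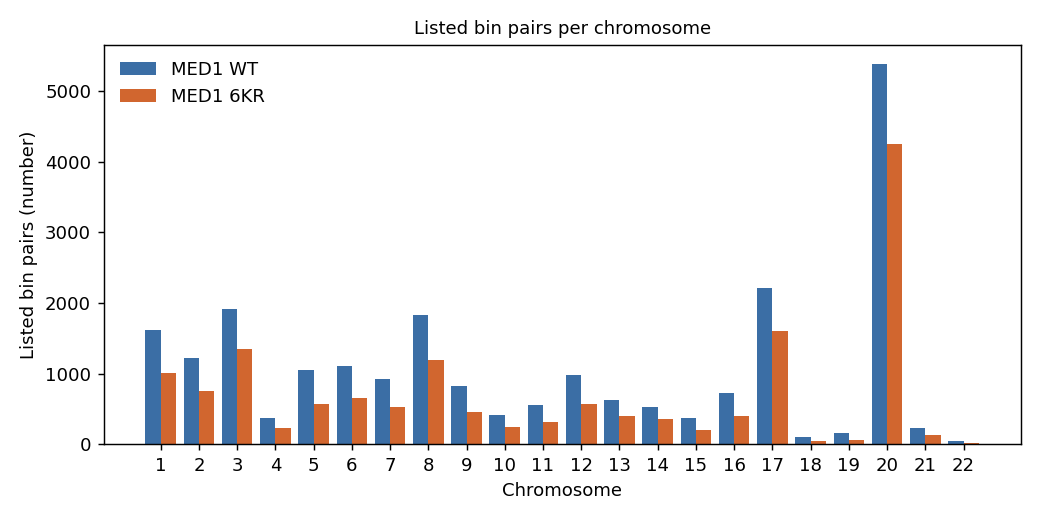
Number of listed bin pairs (y axis) on each autosome (x axis) in the MED1 WT and MED1 6KR libraries, 1 bar per library. Chromosome 20 stands highest, with 5386 pairs in WT and 4249 in 6KR, and the 6KR bar is the lower on all 22 autosomes.

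Most of the 6KR interactions were also WT interactions. Of the 6KR pairs, 66.2% (65.4 to 67.0) were listed in WT, and of the WT pairs, 43.8% (43.1 to 44.4) were listed in 6KR, 10146 pairs in all. On chromosome 20, 61.3% of WT pairs were shared, on chromosome 17 50.9%, on chromosome 3 45.3%, and on chromosome 22 14.6%. When both ends could differ by 1 bin, the shares were 86.9% of 6KR pairs and 68.8% of WT pairs. The 6 shifted lists gave at most 0.556%. The share followed the read count. Among WT pairs with 12 to 14 reads, 20.4% (19.4 to 21.5) were listed in 6KR, against 82.2% (78.7 to 85.3) of those with 100 or more reads. In the other direction the shares were 46.7% (45.1 to 48.3) and 89.8% (86.3 to 92.6).

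**Figure D2:**
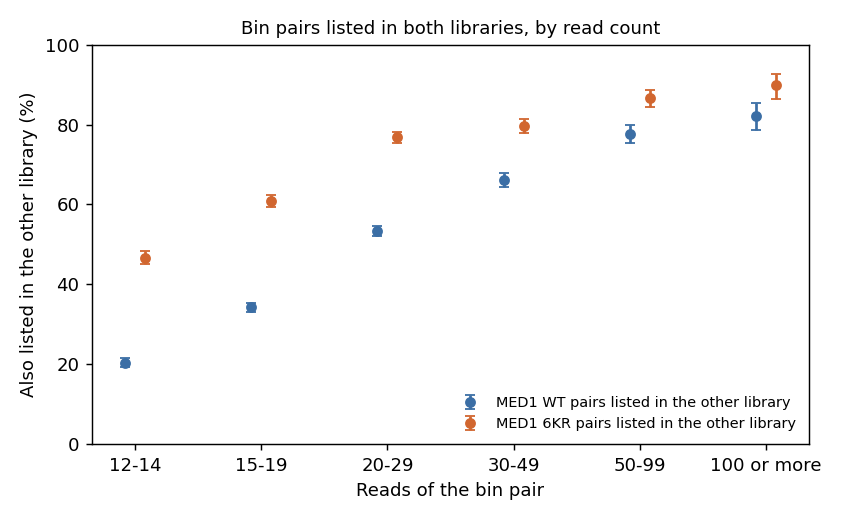
Share of listed bin pairs also listed in the other library (y axis, percent) by the number of reads of the pair (x axis), for MED1 WT and MED1 6KR. Points are shares and bars exact 95% intervals for counting error. The share of WT pairs climbs from 20.4% at 12 to 14 reads to 82.2% at 100 or more.

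Contacts over 2 Mb were concentrated on chromosome 20 in both libraries. Those with the most reads linked the region of ZNF217, a zinc finger gene amplified in breast cancer, with that of BMP7, which encodes a secreted growth factor. The bins at 53570001 to 53580000, in ZNF217, and 57270001 to 57280000, next to BMP7, lay 3700 kb apart and had 504 reads in WT and 353 in 6KR, 140 and 105 times the expected signal. The neighbouring pair of the ZNF217 bin with BMP7 itself, at 57260001 to 57270000, had 340 and 289 reads. Both were chosen after their values were seen. Among windows of 1 Mb on chromosome 20, those starting at 53 and 57 Mb shared 742 pairs in WT and 704 in 6KR, those at 47 and 50 Mb 658 and 604, and those at 47 and 53 Mb 633 and 396. Of the pairs over 2 Mb, 95.6% in WT and 96.7% in 6KR lay on chromosome 20.

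Pairs over 2 Mb made up 11.8% (11.3 to 12.2) of the WT list and 14.4% (13.9 to 15) of the 6KR list, 2726 and 2212 pairs, with a ratio of 0.811 (0.767 to 0.859). Every shorter distance class had a lower ratio, from 0.629 for 50 to 100 kb to 0.677 for 1000 to 2000 kb. The median distance was 250 kb in both lists, with quartiles of 150 and 440 kb in WT and 150 and 480 kb in 6KR. In lists of equal length the difference of the medians, 6KR minus WT, was -30 kb (-40 to -20). With a minimum of 20 reads it was 20 kb (10 to 30), so its direction depended on the setting.

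The contacts listed in both libraries had nearly the same strength. The median log2 change of observed over expected was -0.0035 (-0.011 to 0.0040), with quartiles of -0.23 and 0.21. Of the 10146 shared pairs, 24 were at least 2-fold higher in 6KR and 32 at least 2-fold lower. On chromosome 20 the median was -0.056 (-0.071 to -0.044), and on the other chromosomes 0.020 (0.012 to 0.030). Shared pairs over 2 Mb had a median of -0.10 (-0.13 to -0.081). The 1287 shared pairs with a mean of 50 or more reads had a median of -0.048 (-0.065 to -0.033). These medians hold only for pairs that passed the limits in both libraries. Simulated lists without a change had a median of 0.041, so an upward shift of that size can arise without a change of contacts. The negative medians go the other way, so the simulated shift does not account for them. Across pairs, which are not replicates, Pearson r of log2 observed over expected was 0.898.

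The pairs listed in both libraries with the most reads, taken over the 2 together, lay in the chromosome 20 amplified region. The bins at 53780001 to 53790000 and 53800001 to 53810000, without a protein-coding gene, had 835 reads in WT and 672 in 6KR, 2.79 and 2.56 times the expected signal. The pair at 54090001 to 54100000 and 54190001 to 54200000 had 626 and 580 reads, 9.56 and 10.4 times the expected signal. The pair at 53800001 to 53810000 and 53820001 to 53830000 had 676 and 499 reads, 2.57 and 2.20 times the expected signal, near the limit of 2. On chromosome 17, the bin with SKA2 and TRIM37, at 59100001 to 59110000, and a bin in VMP1, at 59830001 to 59840000, had 641 and 522 reads, 71.5 and 65.6 times the expected signal, and this pair was chosen after its values were seen. Of the pairs listed in WT alone, those with the most reads lay on chromosome 20. The bins from 53760001 and 53780001 had 653 reads, those from 53620001 and 53650001 had 456, and those from 47540001 and 47560001 in NCOA3 had 426. Of the pairs listed in 6KR alone, the bins from 61790001 and 61810001 in BRIP1 had 366 reads, those from 61720001 and 61750001 in BRIP1 had 331, and those from 47310001 and 47330001 in ZMYND8 had 305. All 6 lay 20 or 30 kb apart at 2.01 to 2.33 times the expected signal, just above the limit of 2.

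A gene-end bin was found in 35.2% (34.5 to 35.8) of WT pairs and 34.2% (33.5 to 35.0) of 6KR pairs, a difference of -0.95 percentage points (-1.92 to 0.021). With a minimum of 20 reads the difference was -2.33 points (-3.76 to -0.89), an interval below 0, and in lists of equal length 0.23 (-0.83 to 1.29). With the WT list thinned, chosen after seeing the data, it was -0.82, from -1.05 to -0.60 over a part of the 50 draws, a range that leaves out counting error in the 6KR list. Any bin of a protein-coding gene took part in 83.6% and 83.4% of pairs. At least 1 listed pair was found for 4020 genes in WT and 2770 in 6KR, 4608 in either.

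The genes with the most interactions lay on 20q in both libraries. BMP7 had 149 pairs in WT and 136 in 6KR, a ratio of 0.913 (0.718 to 1.16). PARD6B, a cell polarity gene, had 125 and 118, a ratio of 0.944 (0.728 to 1.22), and ZMYND8, a chromatin reader, 101 and 79, a ratio of 0.782 (0.575 to 1.06). NCOA3, a coactivator of the estrogen receptor, had 94 and 72, a ratio of 0.766 (0.556 to 1.05), and SULF2, a sulfatase, had 93 and 65, a ratio of 0.699 (0.501 to 0.970). BCAS1 had 78 and 69, a ratio of 0.885 (0.630 to 1.24). Without pairs over 2 Mb, chosen after seeing the data, the log2 ratio of BMP7 turned from -0.13 to 0.42 and that of PARD6B from -0.082 to 1. Of the 110 genes with 10 or more pairs in at least 1 library, 80 lay on chromosomes 1, 3, 17 and 20. In 6KR, 92 of the 110 had fewer pairs, 10 had more and 8 had the same number, with a median log2 ratio of -0.36 against -0.60 for the lists.

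Relative to the list lengths, 5 genes had at least 2-fold fewer pairs in 6KR. C3orf49, on chromosome 3 at 63779707 to 63848636, had 11 pairs in WT and 1 in 6KR, a ratio of 0.091 (0.0021 to 0.625). RRM2B, a ribonucleotide reductase subunit induced by p53, on chromosome 8 at 102204501 to 102238961, had the same numbers. The neighbours DTWD1 and FAM227B on chromosome 15, which share a bin, each had 18 and 3 pairs, a ratio of 0.167 (0.031 to 0.571). RPL30, a ribosomal protein gene, had 10 and 2, a ratio of 0.200 (0.021 to 0.939). Next came HBP1 with 11 and 3 pairs, GPRC5B with 10 and 3, CENPF, a kinetochore gene, with 12 and 4, TFAP2C, a luminal transcription factor, with 13 and 5, ZHX3 with 13 and 5, and SNRNP48 with 14 and 6. The log2 ratio of C3orf49 was -2.58 and ranged from -2.58 to -0.69 over the alternatives, that of DTWD1 and FAM227B was -2.25, from -2.32 to -0.81, and that of RPL30 was -1.87, from -2.81 to -0.79. That of RRM2B was -2.58, from -2.58 to -1.05 where a pair was left, while with a minimum of 20 reads it had none in either library. In lists of equal length the values were -1.32 for C3orf49, -2 for RRM2B, -1 for RPL30 and -0.81 for DTWD1 and FAM227B, outside their interval, and that of ZHX3 turned from -1.22 to 0.58. There 0 genes had at least 2-fold fewer pairs and 5 had more.

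Another 3 genes had at least 2-fold more pairs relative to the list lengths. HIPK1, a kinase gene on chromosome 1 at 113929324 to 113977869, had 6 pairs in WT and 13 in 6KR, a ratio of 2.17 (0.768 to 6.95), and its neighbour OLFML3, which shares a bin, had 5 and 12. REN, the renin gene, had 7 and 10, a ratio of 1.43 (0.491 to 4.42). ERN1, a sensor of unfolded protein, had 11 and 14 pairs, NFATC2 9 and 11, ANAPC13 11 and 13, RGS16 9 and 10, TEX14 12 and 13, EYA2 50 and 53, BRIP1 24 and 25, and PPM1D 19 and 19. With a minimum of 20 reads the log2 ratio of REN turned from 0.46 to -0.26 and that of ANAPC13 from 0.22 to -1.58, and with every bin of the gene body that of HIPK1 turned from 1 to -0.14. At an fdr of 0.0001 the counts were 0 fewer and 1 more, and none of the 5 genes with fewer kept 10 pairs: RRM2B and RPL30 each had 5 in WT and 0 in 6KR, DTWD1 and FAM227B 5 and 1, and C3orf49 3 and 1. With every bin of the gene body, chosen after seeing the data, the counts were 32 and 9.

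**Figure D3:**
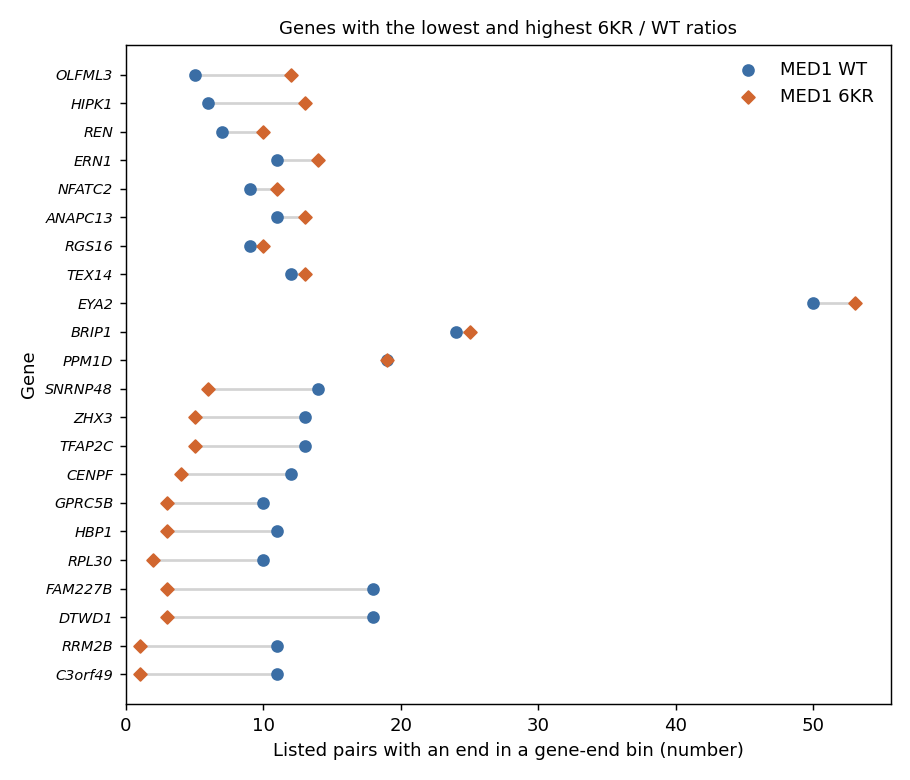
Number of listed pairs with an end in a gene-end bin (x axis) in MED1 WT (circles) and MED1 6KR (diamonds) for the genes with the lowest and highest ratios (y axis), joined by grey lines. C3orf49 went from 11 to 1 pairs and HIPK1 from 6 to 13.

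Estrogen-induced genes had 52 pairs in WT and 29 in 6KR, a pooled ratio of 0.558 (0.341 to 0.895), an interval that includes the 0.661 of the lists. Of the 21 members with a pair, 15 had fewer in 6KR, 2 more and 4 the same number. MYC had 7 pairs in WT and 1 in 6KR, a ratio of 0.143 (0.0032 to 1.11), and CCND1, the cyclin D1 gene, 8 and 5. CELSR2 had 3 and 6, and ABAT 3 in both. The median log2 ratio of -1 (-1 to 0) lay at percentile 12.0 of the matched random lists. At an fdr of 0.0001 it was -1, at percentile 8.01, and with the WT list thinned -0.42, at percentile 5.98. With bins within 5 kb of a gene end it was -0.63, at percentile 38.55. In lists of equal length, which drop weaker pairs from WT alone, it was 0, at percentile 48.5.

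Luminal identity genes had 76 and 51 pairs, a ratio of 0.671 (0.461 to 0.969), with 10 of 16 members with a pair lower in 6KR and 3 higher, and a median log2 ratio that turned from -0.84 to 0.16 in lists of equal length. Besides TFAP2C, GATA3, a luminal transcription factor, had 5 and 2 pairs. The luminal keratin genes KRT8 and KRT18, which are neighbours and have bins in common, had 8 and 8, and 8 and 9. FOXA1, a pioneer factor, had 12 and 11 and GRHL2 15 and 9, both chosen after their values were seen. Basal and mesenchymal genes had 15 and 4 pairs, a ratio of 0.267 (0.064 to 0.837), with 7 of 8 members with a pair lower, and a ratio of 0.154 without SNAI2. Their median lay at percentile 20.9.

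Genes of MCF7 amplified regions had 973 pairs in WT and 756 in 6KR, and in the lists as deposited this was the 1 list of 15 whose interval, 0.777 (0.706 to 0.855), lay above the ratio of the lists. All its members with a pair lay on chromosomes 17 and 20, whose own ratios were 0.727 and 0.789. The value thus does not set these genes apart from other pairs of their chromosomes. Distinct pairs, counted after seeing the data, were 854 and 669, a ratio of 0.783 (0.707 to 0.868). In lists of equal length the order turned, with a pooled ratio of 0.955 against 1, though this setting drops the pairs with the highest fdr from WT alone. With the WT list thinned the pooled ratio was 0.910 against 0.943. Of its 22 members, 21 had a pair, and 19 of these had fewer in 6KR. PREX1 had 39 and 20 pairs and RPS6KB1, the S6 kinase gene, 53 and 33. The median of the list lay at percentile 62.0 among random lists drawn from genes with as many pairs, and at 4.99 in lists of equal length. Acetyltransferases, deacetylases and cofactors had 100 and 75 pairs, of which NCOA3 held 94 and 72, and without it the ratio was 0.500. KAT5, an acetyltransferase, had 3 and 2. Mediator subunits had 12 and 5 pairs, a ratio of 0.417 (0.115 to 1.27), with 5 of 8 members with a pair lower, and a ratio of 0.273 without MED22. Their numbers depended on the setting. They were 5 and 4 at an fdr of 0.0001, and 4 and 4 without chromosomes 1, 3, 17 and 20. With the WT list thinned they were 5 and 5, but with bins within 5 kb of a gene end 16 and 5.

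Cytosolic ribosomal protein genes had 27 and 13 pairs, a ratio of 0.481 (0.228 to 0.966), with 6 of 11 members with a pair lower. RPL30 held 10 and 2 of these, RPL35 had 4 and 3, and without RPL30 the ratio was 0.647. Targets of p53 had 32 and 25 pairs, a ratio of 0.781 (0.444 to 1.36), and 4 of 7 members with a pair had more in 6KR. Their median log2 ratio of 0.58, at percentile 97.4, had the opposite sign to the pooled number. To that number RRM2B gave 11 and 1 and PPM1D, in an amplified region of chromosome 17, 19 and 19. The members with more were GADD45A, SESN1 and ZMAT3, each at 0 and 1, and MDM2 at 1 and 2, so the median rested on single added pairs. Without chromosomes 1, 3, 17 and 20 the list had 12 and 4 pairs, a ratio of 0.333, with the median still 0.58. The median turned to -0.63, at percentile 68.8, with bins within 5 kb of a gene end, and to -1, at percentile 16.2, with every bin of the gene body. Cell cycle genes had 18 and 12 pairs, with CDK6 at 4 and 2 and CCNE2 at 3 and 3. Cohesin and CTCF genes had 7 and 5, with NIPBL, the cohesin loader, at 2 and 4 and a ratio of 0.200 without it.

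The remaining lists also had under 10 pairs per library. Oxidative and heat stress genes had 8 and 7 pairs, with GCLC at 4 and 3. Hypoxia and glycolysis genes had 8 in both, with HK2, a hexokinase gene, at 2 and 4 and a ratio of 0.667 without it. Immune cell genes had 9 and 5, a ratio of 0.556 that was 0.833 without CD79B. Interferon-induced genes had 2 and 5 when counted per member, a ratio of 2.50 (0.409 to 26.3), but OAS1 and OAS3 share a bin and its 2 pairs in 6KR, and the distinct pairs, counted after seeing the data, were 2 and 3, a ratio of 1.5 (0.172 to 18.0). With the shared bin counted once their median log2 ratio was 0. Cholesterol and lipid synthesis genes had 5 and 3, with SCD at 2 and 3 and 0 in 6KR without it. The median of 10 of the 15 lists took the opposite sign under at least 1 alternative. None of the 15 intervals lay wholly below the ratio of the lists.

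**Figure D4:**
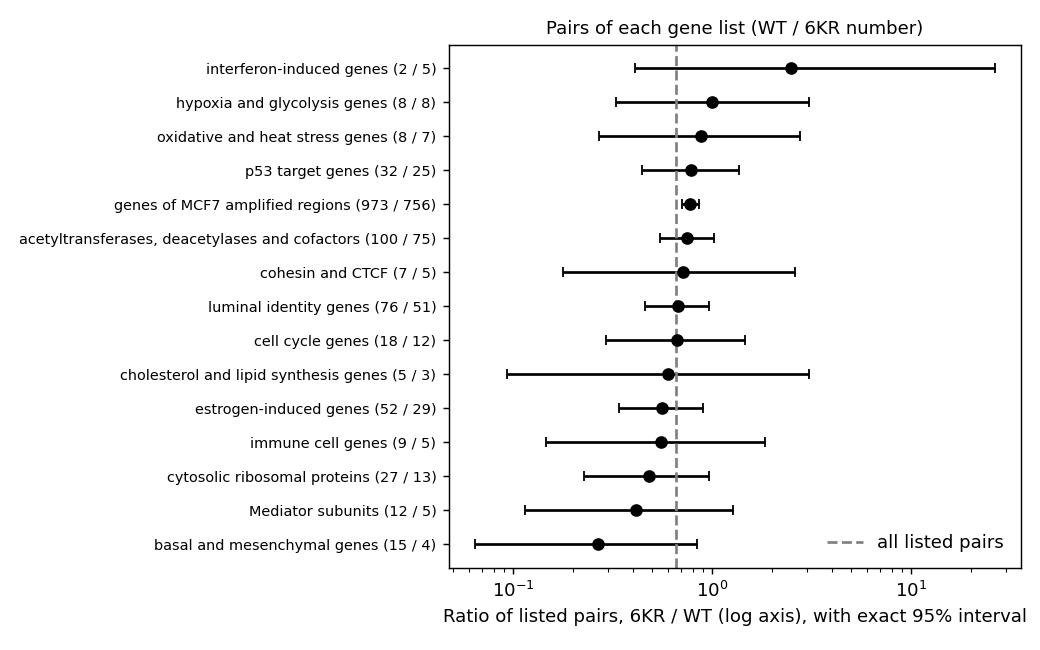
Ratio of listed pairs, 6KR over WT, pooled over the members of each gene list (x axis, log scale), with exact 95% intervals for counting error. Numbers beside the names are WT and 6KR pairs, with a pair counted once for each member it touches, and the dashed line marks the ratio of the whole lists, 0.661. In these lists as deposited the interval of the amplified genes alone lies above it. Those with a pair lie on chromosomes 17 and 20, whose own ratios are 0.727 and 0.789. In lists of equal length, where WT alone lost the pairs with the highest fdr, the ratio of the amplified genes, 0.955, lies below 1.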

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

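Thinning, leaving out pairs over 2 Mb or chromosome 20, the gene body, genes within 1 bin, pooled list numbers and members that share a bin counted once were chosen only after the results were seen. The fixed check of GC content and CviQI sites was not run, the 5-prime end was replaced by both gene ends, and with 1 library per group no replicate could be left out. The ratio of list lengths stayed below 1 except in lists of equal length, which fix it at 1, and the counts of genes past 2-fold ranged from 0 to 32 fewer and 0 to 9 more. These counts need 10 pairs in a library, so stricter limits can lower them by the number of pairs alone. At an fdr of 0.0001 the log2 ratio was -2.58 for RRM2B and RPL30, but shrank from -2.25 to -1.58 for DTWD1 and FAM227B and from -2.58 to -1 for C3orf49. In lists of equal length that of DTWD1 and FAM227B shrank to -0.81, outside their interval. Of 376 values of 47 named genes, 369 stayed within their counting interval, but 33 of the 376, in 19 genes, had the opposite sign, 4 of them outside the interval (ANAPC13, BMP7, PARD6B and ZHX3). The 369 include values of 0 without a pair in either library, so they overstate stability. Examples are MED1, which had no pair and no interval, and ESR1 at an fdr of 0.0001. KAT5 turned from -0.42 to 1.58 in lists of equal length, and with 20 or more reads SCD turned from 0.42 to -1.58 and HK2 from 0.74 to -1. Of 122 list medians, 116 stayed within their interval and 21, in 10 lists, had the opposite sign, among them cohesin and CTCF, from -1 to 1 at an fdr of 0.0001, and luminal identity genes, to 0.16 in lists of equal length. The values that turned sign all had a counting interval that included no change. The read limits of the lists set what depth can show: a pair below 12 reads had no value.

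At an fdr of 0.0001 the ratio was 0.687, the WT share 44.7%, the distance difference 10 kb, the shared median -0.017, and 0 genes had fewer and 1 more. With 20 or more reads the WT share was 47.4%, the distance difference 20 kb (10 to 30), the gene-end difference -2.33 points, and 1 gene had fewer. Among pairs of 100 kb or more the distance difference was 10 kb. In lists of equal length the values were a ratio of 1, a share of 53.6%, -30 kb, 0.23 points, 0 genes fewer and 5 more. Without chromosomes 1, 3, 17 and 20 they were 0.590, 35.2%, -10 kb, a shared median of 0.035 and 0 genes more. Within 1 bin the share was 68.8%, and for WT pairs at an fdr of 0.0001 against the whole 6KR list 54.5%, since these settings count more matches or weigh stronger pairs. With 1 pair per cluster they were 0.679, 25.7% and -10 kb. Raw read counts gave a shared median of -0.17. Bins within 5 kb of a gene end gave 12 genes fewer and 5 more, a minimum of 20 pairs 0 and 0 by construction, since none of the genes past 2-fold had over 18, and scaling by the median gene 8 fewer. Without pairs over 2 Mb the ratio was 0.641, the share 40.6% and the shared median 0.012. Without chromosome 20 these were 0.622, 38.5% and 0.020, with a distance difference of -10 kb. Every bin of the gene body gave 32 genes fewer and 9 more, and genes within 1 bin 1 and 0. Thinned WT, at a depth of 0.860, gave a ratio of 0.943, a share of 53.4%, a shared median of -0.062 and 2 genes fewer. At a depth of 0.901 it stayed 1.16 times as long as the 6KR list, with a share of 51.0%. Apart from the constructions named, the cause was not tested.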

Other observations

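Chosen only after the results were seen were the windows of 2 Mb, the expected-count depth and the lack of scaling as further settings for robust pairs, the test of rearranged DNA and the test of the pairs of genes with 2-fold fewer interactions, with its values per gene, at 20 or more reads and in lists of equal length. For the first pattern, the verdict was made to need both depth estimates after they were found to differ, and for the third to need folds nearer to 0 at 20 or more reads in all 5 genes, each with a pair left.

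Of 209 windows of 2 Mb with 40 or more pairs over both libraries, 208 had fewer pairs in 6KR, with a median ratio of 0.655. The lowest ratio was that of chromosome 15 from 48 to 50 Mb, which holds DTWD1 and FAM227B, with 82 pairs in WT and 18 in 6KR, 0.220 (0.124 to 0.369). Its 74 pairs listed in WT alone had a median of 15 reads, and 28.0% of its WT pairs had a 6KR pair within 1 bin. The 8 pairs listed in both libraries had 144 reads in WT and 134 in 6KR. On chromosome 6, the windows from 40 to 42 Mb and from 42 to 44 Mb followed, with 39 and 12 pairs and 42 and 13 pairs.

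The first pattern was the shorter 6KR list. Lower depth of the 6KR library is a candidate explanation, and thinning the WT list to a depth of 0.860 left it 1.06 times as long as the 6KR list, within the bound of 1.1 set beforehand, but at the depth of 0.901 from expected counts it stayed 1.16 times as long (1.16 to 1.17 over 50 draws). Loss of pairs near the limits of the lists is another: pairs with at least 50 reads and observed over expected of at least 4, with the reads scaled by depth, were 0.984 times as many in 6KR (0.880 to 1.101) at the first depth, but 0.863 (0.769 to 0.969) at the second and 0.700 (0.618 to 0.791) without scaling. Of these 636 WT pairs, 85 lay outside chromosomes 1, 3, 17 and 20. There the ratios were, in the same order, 0.929 (0.675 to 1.28), 0.753 (0.536 to 1.05) and 0.459 (0.306 to 0.678). The first depth was itself estimated from strong pairs, so it can absorb a loss common to them. Simulated lists that differed in this depth alone had a ratio of 0.862, against the 0.661 observed, though they drew no pair from outside the WT list. Both were redrawn from the WT list and had already lost pairs near the limits, so 0.862 does not show what depth alone does. The deposited WT list kept 70.1% of its pairs when thinned to the first depth. Depth, weak pairs and an effect of 6KR MED1 on many contacts cannot be told apart with 1 library per group and no library totals.

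The second pattern was the set of contacts over 2 Mb on chromosome 20. Rearranged and amplified DNA that placed distant blocks side by side is a candidate explanation, and 78.0% of these pairs in WT and 79.6% in 6KR fell in 3 pairs of 1 Mb windows. Their median observed over expected, 7.53 in WT against 3.31 for pairs of 100 to 500 kb, is partly set by the limits of the lists, which at a low expected signal pass only high ratios, and long contacts between separate blocks would also cluster, so the test does not tell these apart. An effect of 6KR MED1 on these contacts was tested against the shared pairs up to 2 Mb on chromosome 20, and the medians differed by -0.080 on the log2 scale, -0.10 (-0.13 to -0.080) against -0.021 (-0.033 to -0.0047). This argues against an effect above the bound of 0.2 particular to the long pairs listed in both libraries, while a smaller one, or one common to chromosome 20, stays open.

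The third pattern was the 5 genes with at least 2-fold fewer interactions in 6KR, C3orf49, RRM2B, DTWD1, FAM227B and RPL30. Loss of pairs near the limits of the lists is a candidate explanation: the 45 pairs of these genes listed in WT alone had a median of 18 reads, from 14 for RRM2B to 20 for RPL30, though 2 pairs of C3orf49 had 218 and 101, at 2.18 and 2.36 times the expected signal, and the 5 pairs listed in both libraries had a median log2 change of 0.12. With 20 or more reads RRM2B had no pair left, and the log2 ratio was -1.32 for C3orf49, -2.32 for DTWD1 and FAM227B and -2.81 for RPL30, while in lists of equal length it was -2 for RRM2B, -1.32 for C3orf49, -0.81 for DTWD1 and FAM227B and -1 for RPL30, so weak pairs are neither shown nor excluded as the source. All WT pairs missing from the 6KR list had a median of 16 reads, so a low read count does not set these genes apart. Simulated lists without a change gave 0 to 1 such genes. They drew no pair from outside the WT list and vary less than real libraries, so this is no chance level for the 5 genes. Of these, DTWD1 and FAM227B share a bin and have the same numbers of pairs. A local effect of 6KR MED1 was not tested and stays open.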
